A study of Danio rerio with 6 samples.

How the data were processed

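RNA was measured by Illumina sequencing of total RNA from whole zebrafish (Danio rerio) embryos at 7 days post fertilization, each sample a pool of 33 to 35 animals. There were 6 pools, 3 kept in embryo medium (control) and 3 in medium with dissolved nucleotides at 10 µM (nucleotide), numbered 1 to 3 in each arm. The labels do not say which nucleotides were used. The columns of the exposed libraries in the deposited table carry the name of another agent, carbon monoxide, in front of the library name. The name of the table itself also gives the comparison as carbon monoxide against control. The library names match the labels of the nucleotide pools, so the columns were assigned by library name and the exposure is named as the labels give it. That mismatch was not resolved here, and every comparison below is between the libraries labelled nucleotide and those labelled control.

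The authors deposited one table of 14681 rows with whole-number read counts per gene and library, not normalized. TopHat2, HTSeq, DESeq2 and the genome build GRCz10 are named in the submitters' processing notes, with no version. The annotation, the strand setting and the treatment of reads that match several places are not given in the sources used here. The authors also deposited a comparison of the arms with a mean count per gene, a log2 fold change and its standard error, a score (the Wald statistic, per the file headers) and a p-value with its adjusted value. The deposited log2 fold changes are shrunken towards 0, as the values show (for actc1b 3.184, against 5.149 here). Of the rows, 69 repeated a symbol with the same 6 counts and were dropped, which left 14612 genes, 477 of them with 0 counts in all 6 libraries. Totals ran from 18690465 to 31556366 counts per library. No read, genome or transcript sequence was used.

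Differential expression was computed from the deposited counts with edgeR 4.0.16 in R 4.3.3. Genes were filtered with filterByExpr (minimum count 10, minimum total 15), which left 13336 genes. Libraries were scaled by the trimmed mean of M values (TMM), and the group term was tested with the quasi-likelihood F test (2-sided), with Benjamini-Hochberg adjustment and a threshold of 0.05. Standard errors (SE) of log2 fold changes were taken as the size of the change divided by the square root of its F statistic. Normalised levels (CPM) are counts divided by the TMM-scaled library total and rescaled to a common total, and their SD is over the 3 libraries of a group. The labels call the pools replicates and do not say whether they came from separate clutches, so p-values measure the spread between these pools.

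The arms share the numbers 1 to 3, and the labels do not say what a number means. Deviations of log2 CPM from the group means correlated across genes at 0.546, 0.625 and 0.617 between same-numbered libraries of the arms, while the 6 differently numbered pairs lay between -0.403 and -0.232. By a rule of more than 0.1 in every pair, the numbers were taken to pair the pools. Deviations from a group mean cancel over its libraries, so the negative values follow from the positive ones and are not separate support. The pairing comes from the counts and not from the labels. In the library names, the number at the end is the same in both arms for pairs 2 and 3 and differs for pair 1. The fit without the number stayed the main one, as chosen before the data were examined, and values with the replicate number as a block are given beside it where they change a call or a count.

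A set of 40 gene lists (pathways, cell types of the whole larva and RNA quality) was fixed before the data were examined, with 1556 members, of which 1295 were matched by symbol or by the current symbol of their NCBI gene number (NCBI RefSeq names of the GRCz12tu assembly). Lists with at least 5 tested members, 39 in all, were tested against the other genes with camera in limma 3.58.1 on voom weights with a preset inter-gene correlation of 0.01, and again with an estimated correlation. Each list was also tested with fry, which asks whether its genes moved one way on balance and does not compare them with other genes. No member of the list of mitochondrially encoded genes was matched, so it was not tested. Named genes are those past the threshold with no overlap between the arms, a mean of at least 10 counts and a symbol that is not a placeholder, up to 12 with the largest rise and 12 with the largest fall, plus up to 4 members of each list with the smallest p. Of these, 1 gene is not reported here. Genes named outside this rule are said to be chosen after their values were seen. Families of related genes, taken by symbol or description, were also grouped after the data were seen and are given as counts.

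The steps were tested on simulated data made from the real means and totals with 200 changed genes. For independent pools without the block, 151 of 13295 genes were called, 20 of them (13.2%) unchanged, and 23.88%, 77.61% and 95.45% of genes changed 1.5-, 2- and 4-fold were recovered. With the block the same data gave 155 calls, 27 of them (17.4%) unchanged, and a recovery of 19.4%, 77.61% and 95.45%. For pools paired by number, the fit with the block called 206 of 13310 genes, 23 of them (11.2%) unchanged, and recovered 80.6%, 95.52% and 98.48%, while the fit without it called 118, none unchanged, and recovered 1.493%, 77.61% and 98.48%. The share of unchanged genes among the calls was thus above the threshold of 0.05 in the first 3 of these fits. Alternatives were other scalings, DESeq2 1.42.0, limma-voom, other filters and thresholds, the block and leaving out each library.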

Results

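The series compared whole zebrafish embryos kept in medium with 10 µM dissolved nucleotides with embryos kept in plain medium, at 7 days post fertilization, and its labels describe it as a test of the response to nucleotides. The deposited table names carbon monoxide in its own name and in the column headers of the exposed libraries, so the agent rests on the labels alone. There were 3 pools of 33 to 35 embryos per arm. The control libraries held 22085223, 18690465 and 23066970 counts, and the nucleotide libraries held 28703789, 25792829 and 31556366.

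The largest differences were rises in genes for ubiquitin, ribosomal proteins, tubulin and actin. The polyubiquitin gene ubc (NCBI gene 777766) was at 5.53 ± 0.494 CPM (SD, n = 3) in control and 673 ± 41.2 CPM (SD, n = 3) in nucleotide pools, a log2 fold change of 6.93 ± 0.140 (SE), or 121-fold (edgeR quasi-likelihood test, adjusted p = 4.6e-07). A further polyubiquitin gene, ubb (550134), rose 17.8-fold. The ribosomal protein genes rpl38 (436759), rpl27 (325618) and rps15 (337148) rose 44.6-, 15.9- and 13.9-fold. rpl38 went from 16.4 ± 0.286 to 731 ± 63.3 CPM (SD, n = 3 each). The actin gene actc1b (58114), expressed in striated muscle, rose 35.5-fold, from 194 ± 41.7 to 6870 ± 2626 CPM, and the alpha-tubulin genes tuba1b (373080), tuba1l2 (573216) and tuba1l (573122) rose 29.2-, 12.5- and 5.98-fold. In control pools rpl38, rpl27 and rps15 lay at 4.03, 6.02 and 6.42 log2 CPM, against a ribosomal protein list median of 10.05. For the genes above, a loss of reads in the control libraries cannot be told apart from a response to the exposure.

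Among the 11 named largest rises, 2 lay outside these families. f13a1a.1 (767742), a gene for the A subunit of coagulation factor XIII, was at 0.236 ± 0.213 CPM in control and 24.8 ± 16.9 CPM in nucleotide pools (log2 fold change 6.74 ± 0.901 SE, edgeR adjusted p = 0.014). Its counts were 0, 8 and 7 in control and 786, 1000 and 194 in nucleotide libraries, and it passed in DESeq2 (6.73, adjusted p = 9.4e-06) and with the replicate block (6.66, adjusted p = 1.72e-07). The authors' deposited table, whose log2 fold changes are shrunken and not comparable with these in size, gives it 0.231 with an adjusted p of 0.147. Its edgeR adjusted p without the block was 0.0947, 0.0602 and 0.0796 without control library 1, 2 or 3. cyp19a1b (60640), the brain form of aromatase, which makes estrogens from androgens, rose 7.77-fold, from 3.28 ± 0.643 to 25.5 ± 7.83 CPM (edgeR adjusted p = 0.00171).

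**Figure D1:**
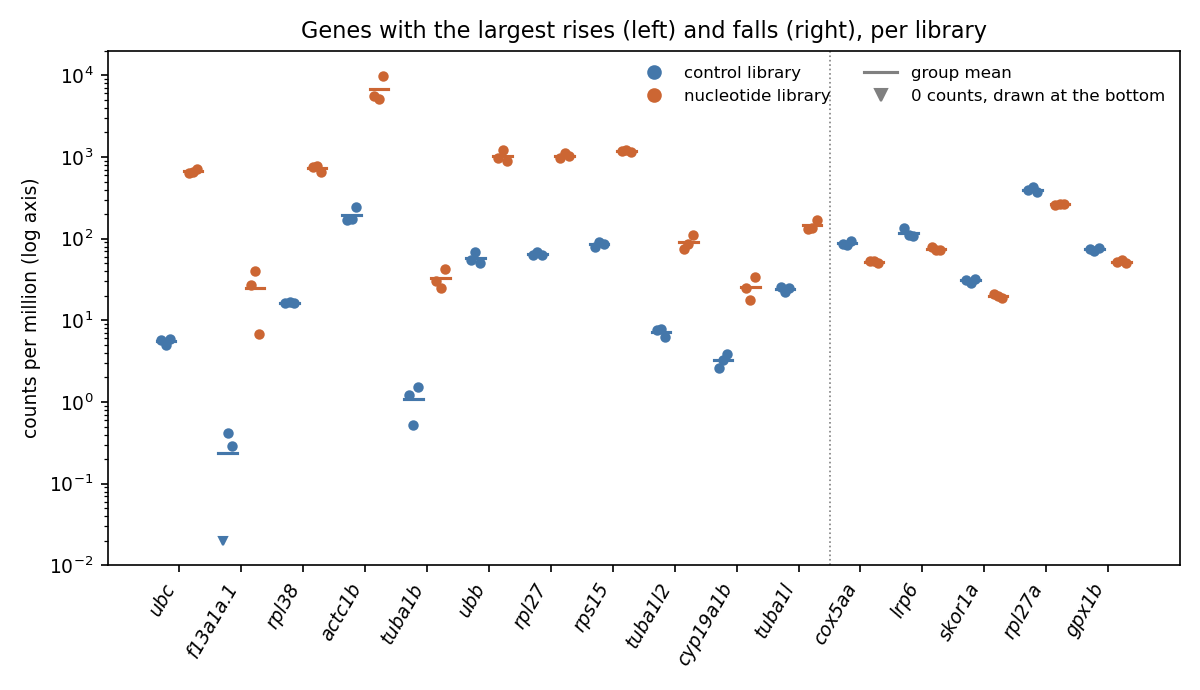
CPM (log axis) of the 11 named genes with the largest rises and the 5 with the largest falls, 1 point per library and a line at the mean of the 3 libraries of each group. In each gene the 3 nucleotide libraries lie on one side of the 3 control libraries, and ubc goes from a mean of 5.53 to 673.

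Without the replicate block 7 genes fell, with log2 fold changes between -0.75 and -0.48 (with the block 1118 fell, 10 of them by at least 2-fold, and DESeq2 called 96 lower). Of the 7, 5 had a symbol other than a placeholder. cox5aa (554101), a subunit of cytochrome c oxidase, went from 87.6 ± 5.82 to 52.2 ± 1.52 CPM (log2 fold change -0.75 ± 0.0883 SE, edgeR adjusted p = 0.00759). lrp6 (100003877), a Wnt co-receptor, had a log2 fold change of -0.65, skor1a (100170817), a transcriptional corepressor, of -0.64, rpl27a (336726), a ribosomal protein gene, of -0.59, and gpx1b (447895), a glutathione peroxidase, of -0.51. The other 2 were zgc:158766 and zgc:194261, named here after their values were seen, at -0.69 and -0.48. The edgeR call of cox5aa was lost without control library 1 (adjusted p = 0.0544), and those of lrp6, skor1a, rpl27a and gpx1b were lost with any single library left out (up to 0.147, 0.149, 0.195 and 0.193), as were those of zgc:158766 (up to 0.13) and zgc:194261 (up to 0.219). zgc:194261 was also lost with all 6 libraries under DESeq2 size factors (0.0502) and with no filter (0.0554).

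In all, 132 of 13336 genes passed an adjusted p of 0.05 in the edgeR test, 125 higher and 7 lower in the nucleotide pools, and 1933 had an unadjusted p under 0.05. With the replicate number as a block, 2550 genes passed, 1432 higher and 1118 lower, among them all 132 in the same direction. Most of the added changes were small, with a median size of 0.346 on the log2 scale among the blocked calls, and 85 rose and 10 fell by at least 2-fold. All 132 genes had no overlap between the arms, as had 21.4% of all tested genes. Chance gives 10% for 6 exchangeable libraries, which pools paired by number are not. With library totals in place of TMM the split was 86 higher and 18 lower, and the median of all genes lay at -0.138 on the log2 scale against -0.014 with TMM. DESeq2 called 398 higher and 96 lower. Leaving out control library 1, 2 or 3 left 39, 72 and 70 genes, and leaving out nucleotide library 1, 2 or 3 left 74, 70 and 80.

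The authors' deposited table, with repeated symbols taken once, has 495 genes at an adjusted p under 0.05 of 12011 with a value, 396 higher and 99 lower. It includes 130 of the 132 genes above.

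The rises included genes of 6 families of related genes, which were grouped after the data were seen and are therefore given as counts without a test. The 3 ubiquitin precursor genes considered rose, as did 10 of 13 alpha- and beta-tubulin genes, 6 of 7 actin genes, 4 of 6 calmodulin genes, 2 of 5 genes for elongation factor 1 alpha and 3 of 33 genes for E2 ubiquitin-conjugating enzymes. With the replicate block 3, 12, 7, 5, 4 and 12 rose in that order, and 1 calmodulin gene fell, calm3a (-0.196, adjusted p = 0.0499), named after its value was seen. Without the block, no member of these 6 families fell in edgeR under TMM, DESeq2 size factors, upper quartile or library totals. None fell in DESeq2 either, and 0 members were lower at an unadjusted p under 0.05 in edgeR. Over all 13336 tested genes 7, 6, 11 and 18 fell under these scalings in that order, and DESeq2 called 96 lower. Called falls were thus rare among all genes, so their absence here is no support for a one-way move. Members of such families can share stretches of sequence, which was not measured here and may differ between the families. The sources do not say how reads matching several copies were counted, so the value of any single member is uncertain. These families, the ribosomal protein genes and the gene not reported here held 55 of the 125 rises (44%), with overlaps counted once. Outside them lay 70 rises and 6 falls. With them left out of the fit 42 genes rose and 2 fell, and the counts were 42 and 2 as well when only the adjustment for multiple tests was made over the remaining genes.

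Of the 74 cytosolic ribosomal protein genes, 27 rose, 1 fell and 46 did not pass, and 43 rose and 3 fell when adjusted over the list alone. The list median was 0.40 on the log2 scale. The list stood above the other genes by camera (adjusted p = 3.39e-26), whereas the adjusted p = 0.92 with an estimated correlation. In fry, which tests whether the genes of a list moved one way on balance and not against other genes, it had an adjusted p of 0.0371 (0.0342 with the replicate block). With the block 46 rose and 5 fell. Levels within the list were uneven in the control libraries, with an SD of log2 CPM over the 74 genes of 1.28 to 1.31, against 0.676 to 0.71 in the nucleotide libraries. The genes with the lowest control levels, rpl38 at 4.03, rpl27 at 6.02 and rps15 at 6.42 log2 CPM, stood at 9.51, 10.02 and 10.21 in the nucleotide pools, where the list median was 10.49.

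**Figure D2:**
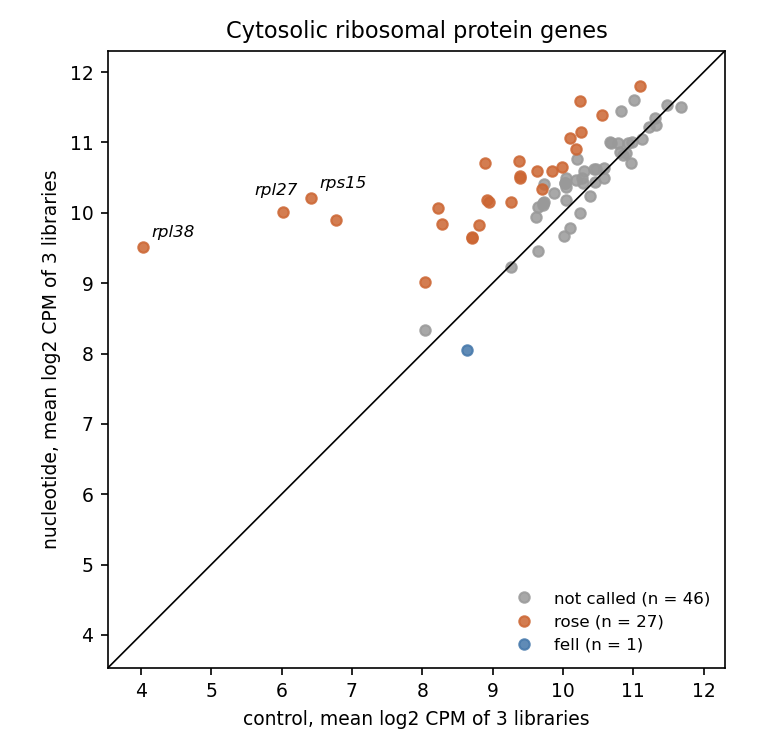
Mean log2 CPM of 3 control libraries (horizontal axis) against 3 nucleotide libraries (vertical axis) for 74 cytosolic ribosomal protein genes, 1 point per gene, with the line of equal levels. The 27 genes that rose (orange) spread to low control levels, down to rpl38 at 4.03, and lie among the other genes on the vertical axis.

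Of 37 tested skeletal muscle markers 4 rose, 0 fell and 33 did not pass in edgeR, and 15 had an unadjusted p under 0.05, each of them higher (12 rose and 0 fell in DESeq2). The 4 were the actin genes actc1b and acta1a and the slow myosin heavy chain genes smyhc3 and smyhc2, with log2 fold changes of 5.15, 1.71, 1.03 and 0.82. Adjusted over the list alone, 12 rose, and with the replicate block 21 rose. Among these were the thin-filament gene tpma (1.25 ± 0.0982 SE) and the muscle creatine kinase gene ckma (0.64 ± 0.0982 SE), named after their values were seen. The list stood above the other genes by camera with the preset correlation (adjusted p = 2.62e-08), whereas the adjusted p = 0.92 with an estimated correlation, and fry gave 0.68 (0.237 with the block). Muscle list genes took 5.487%, 5.101% and 6.065% of counts in the control libraries and 6.456%, 6.268% and 9.524% in the nucleotide libraries, so the nucleotide library 3 stood apart. These shares include actc1b, with 3927, 3317 and 5787 counts in the control and 158478, 128838 and 285014 in the nucleotide libraries. Of 26 markers of vascular endothelium and heart, 2 rose, the cardiac actin gene actc1a (2.06) and the ventricular myosin gene vmhc (0.60), and the list as a whole did not pass in camera (adjusted p = 0.184, and 0.0786 with the block), while fry gave 0.68 without the block and 0.0342 with it. In edgeR without control library 1, actc1b alone of these 6 genes still passed (adjusted p of 0.0544 for smyhc3, 0.0668 for actc1a, 0.176 for smyhc2, 0.198 for acta1a and 0.229 for vmhc). smyhc2 was also lost without control library 2 or 3 or nucleotide library 2, acta1a without control library 2 or nucleotide library 2 or 3, and vmhc with any single library left out.

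Histone genes were listed as a sign of RNA quality, since the messages of replication-dependent histones lack a poly(A) tail. Of the 10 tested, 2 rose, h3f3d and h3f3b.1, both for the replacement histone H3.3, whose messages carry such a tail, the former 2.13-fold and the latter from 112 ± 1.99 to 224 ± 15.1 CPM (SD, n = 3 each), and 4 rose when adjusted over the list alone (camera adjusted p = 0.00264, fry 0.432, adjusted p = 0.92 with an estimated correlation). With the block 5 rose, and fry gave 0.0342. The list was higher in the same comparison as the families, the ribosomal protein genes and the muscle markers, but the 4 members with the smallest p (h3f3d, h3f3b.1, h3f3c and h3f3a) were all H3.3 genes, whose messages do not have the property for which the list was made. Both genes encode the same protein, so their counts are uncertain where copies share sequence.

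A further 3 lists passed in camera with 0 members past the threshold over all genes in edgeR. At an unadjusted p under 0.05 these held 5 macrophage and neutrophil genes, 1 pancreas gene and 7 immediate-early genes, and DESeq2 called 1, 0 and 1 of them, the called ones higher. The macrophage and neutrophil markers had a median of 0.20 (camera adjusted p = 0.0368), with the actin regulator coro1a at 0.40 and the transcription factor gene spi1b at 0.51, and 6 of 29 rose and 1 fell with the block. Exocrine pancreas digestive enzymes had a median of -0.16 (camera adjusted p = 0.0368), with the chymotrypsin-like gene ctrl at -0.31 and the elastase gene ela2l at -0.24, and 5 of 17 fell with the block. Immediate-early genes had a median of -0.23 (camera adjusted p = 0.0428), with klf4 at -0.81, egr2b at -0.44 and mafba at 0.50, and 6 of 31 fell and 2 rose with the block. Adjusted over the list alone, 0 pancreas and 0 macrophage and neutrophil genes passed, and 1 immediate-early gene, mafba, rose. For each of the 3 lists the adjusted p = 0.92 with an estimated correlation, and fry gave 0.68, 0.698 and 0.698 in that order. In the same comparison the skeletal muscle and histone lists were higher (camera adjusted p = 2.62e-08 and 0.00264, both adjusted p = 0.92 with an estimated correlation), and nucleotide library 3 stood apart with 9.524% of counts in muscle list genes.

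These 3 calls did not hold with every single library left out, where fewer samples enter. The macrophage and neutrophil list had an adjusted p of 0.0816 without control library 3, 0.0681 without nucleotide library 1 and 0.0976 without nucleotide library 2. The pancreas list had 0.301 without control library 2 and 0.228 without nucleotide library 3. The immediate-early list had 0.112 and 0.136 without control library 1 or 3 and 0.308 without nucleotide library 1. Over 13 alternative settings the macrophage and neutrophil, pancreas and immediate-early lists passed in 7, 8 and 7. Their highest adjusted p in camera or fry was 0.92, 0.92 and 0.932.

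With the replicate block 11 lists passed in camera, of which 5 did not pass without it when all 6 libraries were used. With an estimated correlation none of the 11 passed, the smallest adjusted p with the block being 0.887. In the same comparison the skeletal muscle and histone lists were higher (camera adjusted p = 3.74e-11 and 0.0132 with the block), and nucleotide library 3 stood apart in its muscle share. The counts of members below stand beside 1432 rises and 1118 falls among all 13336 tested genes with the block. Of 20 genes of the glucocorticoid axis and response 5 fell with the block, among them pck1, the gluconeogenic enzyme gene, at -0.63 ± 0.0843 (SE), and the list had an adjusted p of 0.0392 against 0.103 without the block. Of 40 circadian clock genes 8 fell and 3 rose, with cry4 at -0.38, cry2b at -0.48 and per3 at -0.26 (0.0458 against 0.251). Of 26 heat shock genes 6 rose and 1 fell, with hspa8 at 1.83, hsp70 at 1.63 and hsp70l at 1.07 (0.0459 against 0.103). The median of these 26 genes with the block was only 0.091, and 7 rose and 4 fell when adjusted over the list alone. Without the block only hspa8 rose over all genes in edgeR, and 3 rose when adjusted over the list alone. DESeq2 without the block called 3 higher, hsp70 among them (1.63, adjusted p = 2.84e-06). Of 22 interferon-stimulated genes 4 rose, with rsad2 at 1.34, dhx58 at 0.62 and stat2 at 0.24 (0.0459 against 0.103). rsad2 had 28, 24 and 56 counts in control and 81, 29 and 279 in nucleotide libraries and was higher in 2 of 3 pairs, and without the block its change went from 1.51 to 0.33 (adjusted p = 0.84) when nucleotide library 3 was left out. Of 29 keratinocyte, ionocyte and mucous cell markers 11 rose and 2 fell, with the claudin gene cldne at 0.49 and the keratin gene cyt1l at -0.55 (0.0392 against 0.165).

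These calls changed as well with single libraries or pairs left out, where fewer samples enter. Without the block, the glucocorticoid list passed without control library 1 (0.0304) or nucleotide library 2 or 3 (0.042 and 0.014), the heat shock list without control library 2 (0.0206) or nucleotide library 1 or 3 (0.0255 and 0.031), the interferon list without control library 2 (0.00132) and the keratinocyte list without control library 3 (0.00629) or nucleotide library 1 (0.0165), while without nucleotide library 3 the keratinocyte list turned to the lower side (0.995). With the block, the keratinocyte list was lost without pair 1, 2 or 3 (0.0974, 0.168 and 0.0808), the glucocorticoid list without pair 1 or 2 (0.0927 and 0.101), the interferon list without pair 1 or 3 (0.371 and 0.212), and the circadian and heat shock lists without pair 2 (0.264 and 0.101). Among the genes named, the change without the block went from -0.657 to -0.379 for pck1 without control library 3, and for cry2b and cyt1l from -0.481 to -0.314 and from -0.56 to -0.364 without control library 1, where hsp70l went from 1.02 to 1.54.

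**Figure D3:**
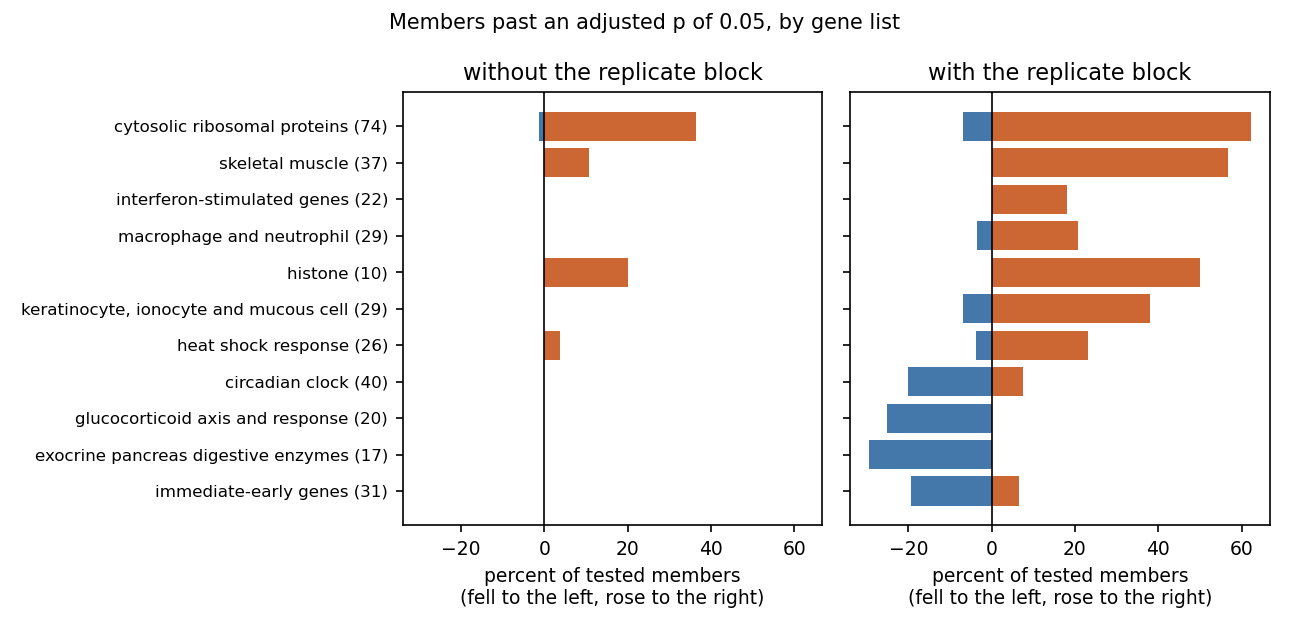
Percent of tested members (number in parentheses) that fell (blue, left of 0) or rose (orange, right of 0) past an adjusted p of 0.05 in edgeR, for the 11 lists that passed in camera with the replicate block, without the block (left panel) and with it (right panel). Cytosolic ribosomal proteins have 27 of 74 members that rose without the block and 46 with it.

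The lists closest to the exposure as labelled did not pass in camera or in fry for a move one way. In fry for changes in either direction, which does not compare a list with other genes, nucleotide catabolism and salvage and purine and pyrimidine synthesis passed with the block (adjusted p = 0.0182 and 0.00595, against 0.589 and 0.371 without it), as did 28 of the 39 lists. None of 34 genes of nucleotide catabolism and salvage passed over all genes in edgeR (camera adjusted p = 0.696), and with the block 3 rose and 2 fell, among the latter dguok, the mitochondrial deoxyguanosine kinase gene, at -0.43. None of 26 genes of purine and pyrimidine synthesis passed (adjusted p = 0.396), and with the block 3 rose and 1 fell, among the former prps1a, a phosphoribosyl pyrophosphate synthetase gene, at 0.50, which also passed when adjusted over the list alone. None of 29 ectonucleotidases and purinergic receptors passed (adjusted p = 0.193), and with the block 2 fell, with the ATP-gated channel gene p2rx7 at -0.35. Over all 13336 tested genes 1432 rose and 1118 fell with the block, a larger share than in each of the 3 lists. At an unadjusted p under 0.05 the 3 lists held 2, 2 and 3 genes, and DESeq2 called 0, 1 and 0.

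In all, 33 lists did not pass in camera without the block, among them those of energy metabolism, stress and immunity and most cell type lists, with adjusted p between 0.103 and 0.968 and medians between -0.146 and 0.191. Within them uqcrh, a subunit gene of respiratory complex III, rose (0.64) in the oxidative phosphorylation list, where cox5aa fell, and gapdh, a glycolytic enzyme gene that is also in the hypoxia list, rose 2.14-fold. hmgb2a, a chromatin protein gene, rose (0.81) in the cell cycle list. With the block 10 of 49 oxidative phosphorylation genes rose and 10 fell. Of 38 glycolysis and gluconeogenesis genes 10 rose and 7 fell with it, and of 32 proteasome genes 10 and 4. Over all 13336 genes 1432 rose and 1118 fell with it. In fry for changes in either direction, the oxidative phosphorylation list had an adjusted p of 5.63e-05 without the block. gapdh and uqcrh no longer passed in edgeR without control library 1, 2 or 3 or nucleotide library 1 or 2 (up to 0.198 and 0.1), nor hmgb2a without control library 1 or 2 or nucleotide library 1 (up to 0.109). In 6 of these lists the median, the mean and the direction of the test differed in sign.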

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

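The settings with a pair, a family or depth removed, and DESeq2 with the block, were chosen after seeing the data. The 132 calls moved by less than 1.5 times with DESeq2 size factors (132), upper quartile (125), library totals (104), limma-voom (127), no filter (129), a mean of at least 10 counts (131) and thinning to equal totals (132). The count was 494 with DESeq2, 308 and 56 at an adjusted p under 0.1 and 0.01, 62 with a log2 change of at least 1, 2550 with the replicate block and 39 to 80 with 1 library left out, where fewer samples enter. It was 2135, 2012 and 1671 with the block and pair 1, 2 or 3 left out, and 1568 with the block in DESeq2. It was 44 (2505 with the block) without the families, the ribosomal protein genes and the gene not reported here. Leaving these out took 56 of the 132 calls with them, and the other 76 came down to 44 when p-values of the same fit were adjusted over the remaining genes. The share of called genes that rose was 94.7%. It was 82.7% with library totals, 80.6% with DESeq2, 84.4% and 98.2% at 0.1 and 0.01, 100% at a log2 change of at least 1, 56.2% with the replicate block and 97.2% to 100% with 1 library left out. It was 59.3%, 57.2% and 60.4% with the block and pair 1, 2 or 3 left out, 63.5% with the block in DESeq2 and 58.3% with the block and without the families. The cause was not tested where the setting does not itself show it.

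Camera called 6 lists, 11 with the replicate block (10, 6 and 11 with pair 1, 2 or 3 left out), 0 with an estimated correlation, with or without the block, where also 0 lists had an unadjusted p under 0.05, and fry, which does not compare a list with other genes, called 1 (ribosomal proteins), or 3 with the block (vascular endothelium and heart and histone as well), and for changes in either direction 8, or 28 with the block. With 1 library left out it called 5 to 9. The keratinocyte, ionocyte and mucous cell list, not called without the block, turned to the lower side without nucleotide library 3 (adjusted p = 0.995, the lowest with 1 library left out being 0.00629). Of the 11 named largest rises, 10 passed in each of 10 alternatives. The exception, f13a1a.1, passed in 7 and was lost without control library 1, 2 or 3 (adjusted p = 0.0947, 0.0602 and 0.0796). Each fall was lost with a library left out: cox5aa in 1 of 10 alternatives and lrp6, skor1a, rpl27a and gpx1b in 6. No named gene changed sign but vtg1, not called in any setting, which ran from -0.102 to 0.152 with 1 library left out. The block changed no call of a named largest rise or fall. At totals of 18690465 to 31556366 counts, genes with a few counts per library, such as f13a1a.1 in the controls, have folds that rest on few reads.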

Other observations

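The tests in this part were chosen after the results were seen. Outside the families and the ribosomal protein list, the genes that rose included snrpd2 (1.83 on the log2 scale), sf3b5 (1.32), u2af1 (1.04), eif4a3 (0.90), hmgb1a (1.02), hdac1 (0.58) and smarcb1a (0.56), together with dynll1, a dynein light chain gene (1.84), cdc42, a small GTPase gene (0.53), and sox2, a neural progenitor transcription factor gene (0.59). They were named after their values were seen and no enrichment was tested, so they stand for no group of genes. snrpd2, u2af1, eif4a3 and dynll1 passed with each single library left out. smarcb1a, hdac1 and cdc42 lost their call with any single library left out. The other 3 lost theirs in most cases, the exceptions being hmgb1a without nucleotide library 2, sox2 without nucleotide library 3 and sf3b5 without control library 3. The noncoding RNA gene rn7sk had 0, 0 and 3 counts in the control libraries and 62, 1863 and 41 in the nucleotide libraries, with an edgeR adjusted p of 0.147 without the block and 8.12e-07 with it.

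With 3 libraries per arm there are 10 splits of the 6 libraries, too few for a share under 0.05. The real split called 132 genes and the highest of the others called 0, and the real split was the 1 split that reached 132. Of the other splits, 3 part all 3 numbered pairs, as the real one does, and 6 part 1 pair. With the replicate block there are 4 exchanges of the arms within pairs, again too few, and the real one called 2550 genes against 0 for the highest other, so 1 of 4 reached that count.

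The first pattern is the rise of ribosomal protein, ubiquitin, tubulin and actin genes. After each library was thinned to 18690465 counts, 96% of the 125 genes that rose still did. Thinning leaves the expected CPM of a gene unchanged, so this test could not decide whether depth was the cause. It shows only that most calls did not need the greater depth of the nucleotide libraries. A candidate explanation is that reads of these genes were lost in the control libraries, for example through a different treatment of reads shared between copies or of conserved sequence. Over all 74 ribosomal protein genes the SD of log2 CPM was higher in the control libraries by 0.595 on average, which lost reads would give, but a response to the exposure that brings low genes up to the level of their family would give it too. These cannot be told apart, as the arms and any difference in their processing coincide. Reads of another organism in the nucleotide libraries were not tested, since no sequence was used.

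The second pattern is the rise of skeletal muscle genes with the replicate block. Reads shared between actin copies are argued against as its whole cause, since the list without actins still stood above the other genes (adjusted p = 1.32e-07, 18 of 34 members rose and 0 fell). Only actins were taken out, so reads shared between other related muscle genes, such as smyhc2 and smyhc3, were not tested. The high muscle share of nucleotide library 3 is argued against as the whole cause, since without pair 3 the list without actins still passed (2.46e-06, 15 members rose and 1 fell), but pair 3 held the largest part, with median differences without actins of 0.119, 0.263 and 0.548 on the log2 scale in pairs 1, 2 and 3. A larger share of muscle in the exposed pools cannot be told apart from a response of muscle genes. Of the 34 members 82.4% had a positive change, and the 10 most abundant ranged from 0.05 to 1.25 on the log2 scale with none that fell. All of these p-values use the preset correlation, and with all 6 libraries none of the 39 lists passed with an estimated one.

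The third pattern is the rise of cyp19a1b and f13a1a.1, of which the former is a known target of estrogen receptors in the fish brain. A list of other estrogen-responsive genes and receptors was drawn up after some values were seen. With the block 1 of its 10 tested genes rose in edgeR (1 rose in DESeq2 without the block), the progesterone receptor gene pgr (0.82, adjusted p = 0.00663, and 0.108 without the block), 1 fell, the vitellogenin gene vtg7 (-2.07, adjusted p = 0.038, and 0.243 without the block, from 14, 14 and 13 counts in control and 6, 6 and 0 in nucleotide libraries), and the median was -0.145. With the block the vitellogenin gene vtg1 was at -0.00228 (upper 95% bound 0.48) and the estrogen receptor gene esr1 at -0.153 (0.325). The highest upper bound among the 10 was 1.15, under the lower bound of 2.67 for cyp19a1b. A rise in them as large as that of cyp19a1b is thus argued against. Estrogen receptor activity throughout the larva cannot be told apart from other causes, as 1 responsive gene rose with the block and the list is short. An action limited to the brain was not tested.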
